A study of Lemna gibba and Lemna japonica and Spirodela polyrhiza with 12 samples.

How the data were processed

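The material was whole fronds of 4 duckweed accessions, Lg7742a, Lj8627, Sp9509 and Wa8730, with 3 biological replicates each and 12 small RNA libraries in all. Per the labels' protocols, RNA enriched for small sizes was made into libraries with the NEXTflex small RNA kit and sequenced on a NextSeq 500. The submitters' processing notes name fastp 0.20.1 and deepTools, without the version of the latter or the role of either. Per the files themselves, loci were called with ShortStack on all replicates of an accession together, against assembly asm202106v1 of Lg7742a, Lj8627 and Wa8730 and assembly asm3v1 of Sp9509. The alignment settings and the thresholds for a locus are not given in the sources used here.

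The value used was the deposited count of reads per locus, a whole number with no normalization by the authors, pooled over the 3 replicates of an accession. Each locus comes with its position, strand, size class and, for microRNA hairpins, lines for the mature and star strands. Mature and star lines repeat part of the reads of their hairpin and were left out of all totals. Size classes were 21, 22, 23 and 24 nt or no call; no locus was called 20 nt. The class names the size that dominates a locus, so reads in 24 nt loci are not all 24 nt long. Each list holds only loci above a minimum that is not given. The smallest count listed was 3 reads in Lg7742a and Lj8627, 5 in Sp9509 and 4 in Wa8730. Total library depth was not used here.

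Pooling decides what can be compared. A locus seen in a single replicate cannot be told from a locus seen in all 3, and no test between accessions is possible. Differences in list length also carry differences in depth and in the smallest count listed. How reads that match several places were put down affects repeats and recent duplicates most, and this matters for 24 nt loci and for both chromosome sets of Lj8627.

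Shares of loci and of reads were given 95% Wilson intervals, ratios of counts a 95% interval from the binomial share of their sum. These intervals cover counting error only: the reads carry no molecular identifiers and are not independent molecules, and loci are not biological replicates. Depth was 5005362 reads in loci for Lg7742a, 5394332 for Lj8627, 7197515 for Sp9509 and 5649845 for Wa8730. By counting error alone a share of reads is precise to about the third digit, while the spread between replicates could not be measured. Ratios of 24 nt to 21 and 22 nt loci, medians of length and reads, loci per 1 Mb window and loci per Mb up to the last locus of each chromosome were computed from the lists. In Lj8627, same-numbered M and T chromosomes were compared with hairpins left out. Hairpins on them were paired where mature strands had the same length, hairpin length and the position of the mature strand differed by at most 10 bp, and no other partner met this, without use of their reads. Hairpins counted as neighbours when under 10 kb apart, and a long locus was over 600 bp.

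The loci named were set by a rule fixed before the data were examined: per accession the 5 hairpins with most reads, the 2 other loci with most reads in each size class, and the longest 24 nt locus. Text gives those a comparison rests on; the T copies of hairpin pairs in Lj8627 outside that rule, and any other locus or window singled out, were chosen after their values were seen. Matching mature strands to 22 microRNA families was planned and not run, since it needs a genome sequence, and loci were not placed in genes or exons for the same reason. No sample column was left unused.

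Alternatives were read minimums of 5, 10 and 100, reads scaled to the accession with the fewest reads in loci, hairpins, top loci, organelles and scaffolds left out, other denominators and weights, other windows, and chromosome pairs left out in turn. Scaled reads were not rounded before the minimum was applied. Computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. On simulated lists of known makeup the 5 classes were recovered exactly in each accession. This checks the reading and summing of the lists, not the size calls or the loci themselves. For 17 simulated hairpin pairs over 200 runs, an even division of reads was called even in 95.0% of pairs, and a division drawn at a share of 0.6 in 5% of pairs.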

Results

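Small RNAs were sequenced from whole fronds of 4 duckweeds, which are small floating aquatic plants of the family Lemnaceae. The accessions were Lg7742a of Lemna gibba, Lj8627 of Lemna japonica, Sp9509 of Spirodela polyrhiza and Wa8730 of Wolffia australiana. Lemna japonica is a hybrid, and its assembly holds a set of chromosomes whose names end in M and a set whose names end in T. Each accession had 3 biological replicates, 12 libraries in all. The locus lists combine the 3 replicates of an accession, so no spread between replicates could be measured and no difference between accessions was tested.

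Reads had been grouped into small RNA loci on each accession's own assembly. Lg7742a had 10022 loci holding 5005362 reads, and Lj8627 had 26073 loci holding 5394332 reads. Sp9509 had 6315 loci with 7197515 reads, against 37162 loci with 5649845 reads in Wa8730. The smallest locus listed held 3 reads in both Lemna accessions, 5 in Sp9509 and 4 in Wa8730. Each locus carries the size that dominates its reads, from 21 to 24 nt, or no size call where too few reads fall within the range that Dicer-like enzymes cut.

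The first comparison asked how the size classes are balanced in the 4 duckweeds. In plants, 24 nt small interfering RNAs guide DNA methylation of repeats, whereas 21 and 22 nt RNAs, microRNAs among them, mostly act on transcripts. Wa8730 stood apart by its 24 nt loci: 30015 loci, 80.8% of its list (95% interval 80.4 to 81.2). The 24 nt class made up 34.5% of the loci of Lj8627 (34.0 to 35.1), 22.7% of those of Lg7742a (21.9 to 23.6) and 16.5% of those of Sp9509 (15.6 to 17.4). In reads the classes were ordered otherwise, since 21 nt loci held most reads in every accession: 79.8% in Lg7742a, 74.5% in Lj8627, 61.3% in Sp9509 and 69.6% in Wa8730.

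Loci called 24 nt held 0.694% of the reads of Lg7742a, 1.10% of those of Lj8627, 0.711% of those of Sp9509 and 12.4% of those of Wa8730. MicroRNA hairpins took most reads in each list. Outside them, 24 nt loci held 51.7% of the reads of Wa8730 (51.6 to 51.8), compared with 3.34% in Lg7742a, 5.22% in Lj8627 and 2.33% in Sp9509. The 22 nt class was largest in Sp9509, where it held 25.7% of all reads, and smallest in Lg7742a at 9.96%. Loci with no size call were the most numerous class in Sp9509, 3139 of 6315 loci or 49.7%, and also in Lg7742a, with 32.3% of loci. The 23 nt class stayed below 0.6% of the reads in all 4 lists.

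**Figure D1:**
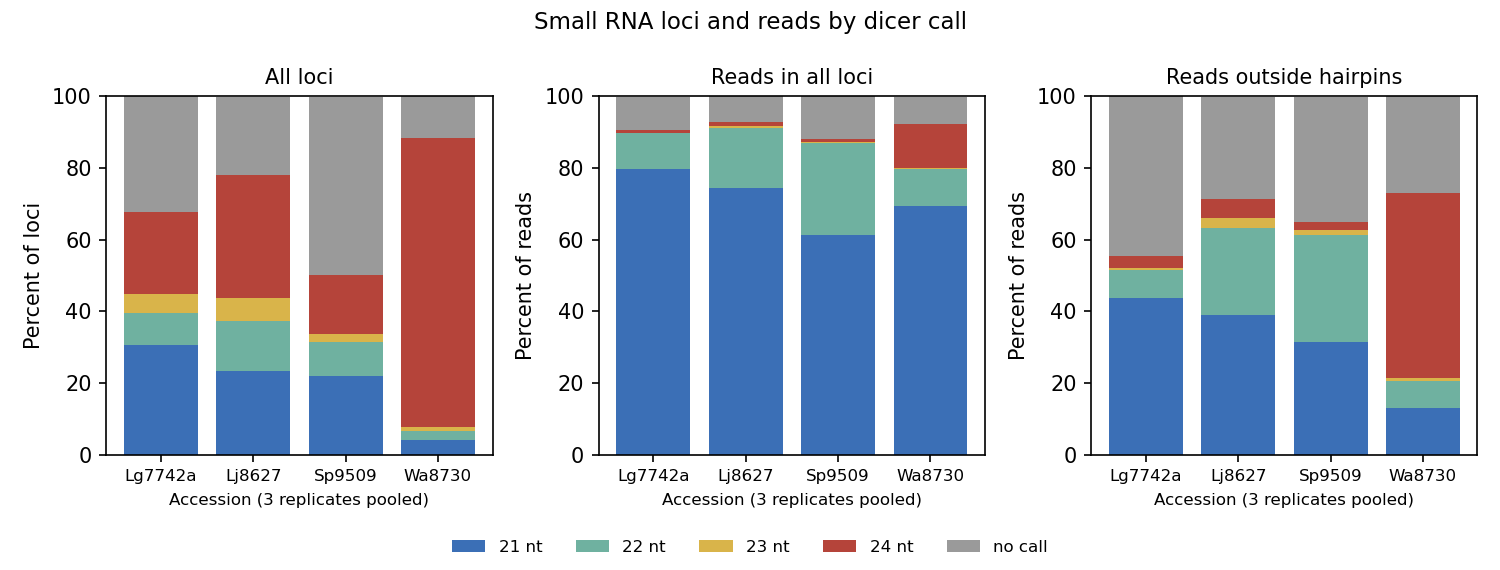
Stacked bars show, for each of the 4 accessions, the percent of loci, the percent of reads and the percent of reads outside microRNA hairpins in each size class. The 24 nt class fills 80.8% of the loci of Wa8730 but 12.4% of its reads, and 51.7% of its reads once hairpins are left out.

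For every locus of 21 or 22 nt, Wa8730 had 12.4 loci of 24 nt (95% interval 11.9 to 12.9). That ratio was 0.927 in Lj8627 (0.901 to 0.954), 0.573 in Lg7742a (0.544 to 0.603) and 0.525 in Sp9509 (0.488 to 0.566). In reads, the corresponding ratio was 0.156 in Wa8730, 0.0120 in Lj8627, 0.00817 in Sp9509 and 0.00773 in Lg7742a. Wa8730 thus had 13.2 times as many 24 nt loci as Lg7742a, 3.33 times as many as Lj8627 and 28.8 times as many as Sp9509. When the 10 loci with most reads were left out of each list, the read ratio of Wa8730 rose to 1.11, so that its 24 nt loci held more reads than its 21 and 22 nt loci together.

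The order of the other accessions depended on the smallest locus counted. With at least 10 reads, 24407 of the 24 nt loci were left in Wa8730, 983 in Sp9509, 980 in Lj8627 and 230 in Lg7742a. After reads were scaled to the accession with the fewest, the same minimum left 20615 in Wa8730, 844 in Sp9509, 728 in Lj8627 and 230 in Lg7742a. Sp9509 kept 94.3% of its 24 nt loci at 10 reads, whereas Lj8627 kept 10.9% and Lg7742a 10.1%. Most 24 nt loci of both Lemna accessions therefore rested on fewer than 10 reads pooled over 3 replicates.

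**Figure D2:**
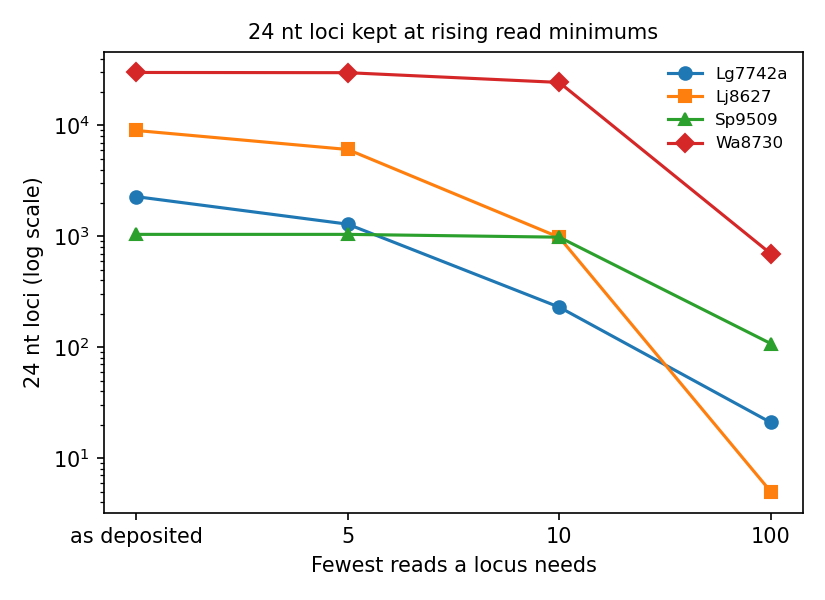
Lines with markers give the number of 24 nt loci per accession, on a log axis, for the lists as deposited and for minimums of 5, 10 and 100 reads. Wa8730 has the most 24 nt loci at each minimum, from 30015 as deposited to 698 with at least 100 reads, and Lj8627 falls from 9002 to 5.

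The second comparison concerned microRNA genes, each listed as a hairpin with its mature strand and the opposite, star strand. Lj8627 had 144 hairpins, Wa8730 117, Lg7742a 83 and Sp9509 81. These few loci held 79.2% of the reads of Lg7742a, 79.0% of those of Lj8627, 76.0% of those of Wa8730 and 69.5% of those of Sp9509. Mature strands accounted for 89.1% of hairpin reads in Lg7742a, 89.7% in Lj8627, 92.5% in Wa8730 and 80.8% in Sp9509, where the star share was also the highest at 4.90%. Most mature strands were 21 nt long: 76 in Lg7742a, 127 in Lj8627, 74 in Sp9509 and 107 in Wa8730.

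A single 21 nt hairpin led the lists of Lg7742a, Sp9509 and Wa8730. In Lg7742a it lay on chr7 from 587386 to 587598 and held 2510804 reads, 50.2% of all reads in loci. The leading hairpin of Sp9509, on chr5 from 6909384 to 6909592, held 20.9%, and that of Wa8730, on chr11 from 16930771 to 16930982, held 28.6%. Lj8627 had 4 leading hairpins of nearly equal reads: a pair on chr7T from 761196 to 761407 and on chr7M from 423952 to 424163, each with 11.9% of reads, and a pair on chr16M from 10407369 to 10407621 and on chr16T from 13276137 to 13276393, each with 11.7%. The hairpins on chr7 of Lg7742a, on chr7M and chr7T, on chr11 of Wa8730 and on chr5 of Sp9509 were alike in length. They were 213 bp long in Lg7742a, 212 bp in Lj8627 and Wa8730, and 209 bp in Sp9509. Another hairpin of Sp9509, on chr13 from 2477625 to 2477833, was also 209 bp long, so length alone does not match hairpins between accessions. In Wa8730 a 21 nt hairpin of 252 bp on chr4, from 1138510 to 1138761, held a further 1356774 reads.

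Most reads of the 22 nt class also came from few hairpins. A hairpin of 127 bp on chr5 of Lg7742a, from 23346760 to 23346886, held 77.0% of the reads in 22 nt loci. The share was 64.5% for a hairpin of 123 bp on chr3 of Sp9509, from 7343199 to 7343321, and 81.3% for a hairpin of 126 bp on chr3 of Wa8730, from 19786737 to 19786862. In Lj8627 a hairpin of 131 bp on chr5M, from 16875103 to 16875233, and its counterpart on chr5T held 34.6% each.

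Hairpins differed in depth. The median hairpin held 7848 reads in Sp9509, 2285 in Lj8627, 519 in Lg7742a and 85 in Wa8730. With at least 100 reads, 114 hairpins were left in Lj8627, 70 in Sp9509, 61 in Lg7742a and 58 in Wa8730, so Wa8730 moved from the second to the last place. Hairpins were not matched to microRNA families, and how reads that match several hairpins were divided is not given in the sources used here.

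Outside hairpins, the loci with most reads were of the 21 nt class in all 4 accessions. They lay on chr19 of Lg7742a from 11944551 to 11945567 with 74860 reads, on chr6 of Sp9509 from 4929309 to 4931137 with 224040 reads, and on chr5 of Wa8730 from 5681203 to 5682315 with 22670 reads. The corresponding 21 nt locus of Lj8627, on chr12M from 2997380 to 2998873, held 58488 reads. A 22 nt locus of 23427 bp on chr7M of Lj8627, from 17083605 to 17107031, held 55159 reads on neither strand in particular. Among loci with no size call, 55217 reads lay on chr4 of Lg7742a from 72301 to 76655, and 123021 on chr1 of Sp9509 from 11544592 to 11546605.

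The third comparison took length, depth and strand of the 24 nt loci. Small interfering RNAs cut from double-stranded RNA come from both strands, and 24 nt loci of Wa8730 and Sp9509 mostly did: 92.9% and 87.2% were assigned to neither strand. The shares were lower in Lj8627, at 72.1%, and in Lg7742a, at 65.6%. Loci of these accessions held a median of 5 reads, against 24 in Sp9509 and 15 in Wa8730. With so few reads a locus can fall on a single strand by sampling alone, so these shares do not compare strand use at like depth. Among 24 nt loci with at least 100 reads, 98.9% of the 698 in Wa8730 and 88.0% of the 108 in Sp9509 were on neither strand. In Lg7742a that held for 4.76% of 21 such loci, and in Lj8627 for 20% of 5, so the deepest 24 nt loci of both Lemna accessions gave reads mostly from a single strand.

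A 24 nt locus held a median of 24 reads in Sp9509, 15 in Wa8730 and 5 in both Lemna accessions. The median length was 424, 420, 414 and 414 bp in Sp9509, Wa8730, Lj8627 and Lg7742a. Medians lay between 414 and 426 bp in every size class of every accession, so they do not set 24 nt loci apart. How far a listed locus extends beyond its reads is not given in the sources used here. In the whole lists, 32.3% of the 24 nt loci of Sp9509 and 25.1% of those of Wa8730 exceeded 600 bp, compared with 4.82% in Lj8627 and 3.82% in Lg7742a. This difference went with reads per locus: at a common minimum of 10 reads the shares were 34.3%, 30.9%, 37.9% and 34.3% in the same order, and the medians 424, 424, 499 and 460 bp. The longest was 9614 bp, on chr2 of Wa8730 from 24180759 to 24190372, and with 2355 reads it was also the 24 nt locus with most reads there. In Lg7742a, 10 loci held 46.7% of the reads of the 24 nt class, led by 1670 reads on the plus strand of chr10 from 5418261 to 5418686. The top 10 in Wa8730 held 1.34%.

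Along the chromosomes, Wa8730 had 85.1 loci of 24 nt per Mb spanned, against 11.5 in Lj8627, 7.52 in Sp9509 and 4.63 in Lg7742a. The summed listed length of 24 nt loci on chromosomes came to 5.03% of the length spanned in Wa8730, 0.539% in Sp9509, 0.50% in Lj8627 and 0.20% in Lg7742a. How much of that length lies beyond the reads is not known. A 1 Mb window held on average 82.8 loci of 24 nt in Wa8730, 11.2 in Lj8627, 7.12 in Sp9509 and 4.53 in Lg7742a. The variance over mean was 19.2, 9.47, 2.61 and 1.86 in the same order, where random placement gives a value near 1. For clustered loci this value also rises with the mean number per window, so it does not rank the accessions by clustering. In Lj8627 part of the variance over mean lay between the M and T chromosomes, since it was 5.08 within M and 2.01 within T. The fullest window held 186 loci, at the start of chr5 of Wa8730. Spans run to the last locus of each chromosome, since assembly lengths were not used here.

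The fourth comparison set both chromosome sets of the hybrid Lj8627 side by side, within the same libraries. Outside hairpins, 24 nt loci were 3.65 times as many on M as on T chromosomes (6771 against 1856, 95% interval 3.47 to 3.84), and M was higher in 21 of 21 chromosome pairs. Loci of 22 nt went the other way, with 1408 on M and 2104 on T, a ratio of 0.669 (0.626 to 0.716), and T was higher in 18 of 21 pairs. The 23 nt class followed the 24 nt class, at a ratio of 2.95 (2.64 to 3.30). The 21 nt class leaned to M, with 3192 against 2580 loci and a ratio of 1.24 (1.17 to 1.30), as did loci with no size call, at 1.56 (1.48 to 1.65). All classes together gave 15800 loci on M and 9016 on T, a ratio of 1.75 (1.71 to 1.80), with M higher in 21 of 21 pairs. With at least 10 reads per locus this lean was nearly gone, at 3284 loci on M and 3229 on T.

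T chromosomes spanned more sequence, 415 Mb against 337 Mb, so that 24 nt loci per Mb differed by a ratio of 4.49. For 22 nt loci the M to T ratio per Mb was 0.824, nearer to equality, and M was denser in 6 of 21 pairs. With at least 10 reads per locus, the M to T ratio of 24 nt loci was 7.26 (791 against 109 loci), that of 22 nt loci 0.396, and that of 21 nt loci turned to 0.866. Reads of the 24 nt class favoured M by 4.44. Reads of 22 nt loci favoured M by 1.91, but by 0.814, that is T, once the 10 loci with most reads were left out. How reads that match repeats of both sets were placed is not given in the sources used here.

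**Figure D3:**
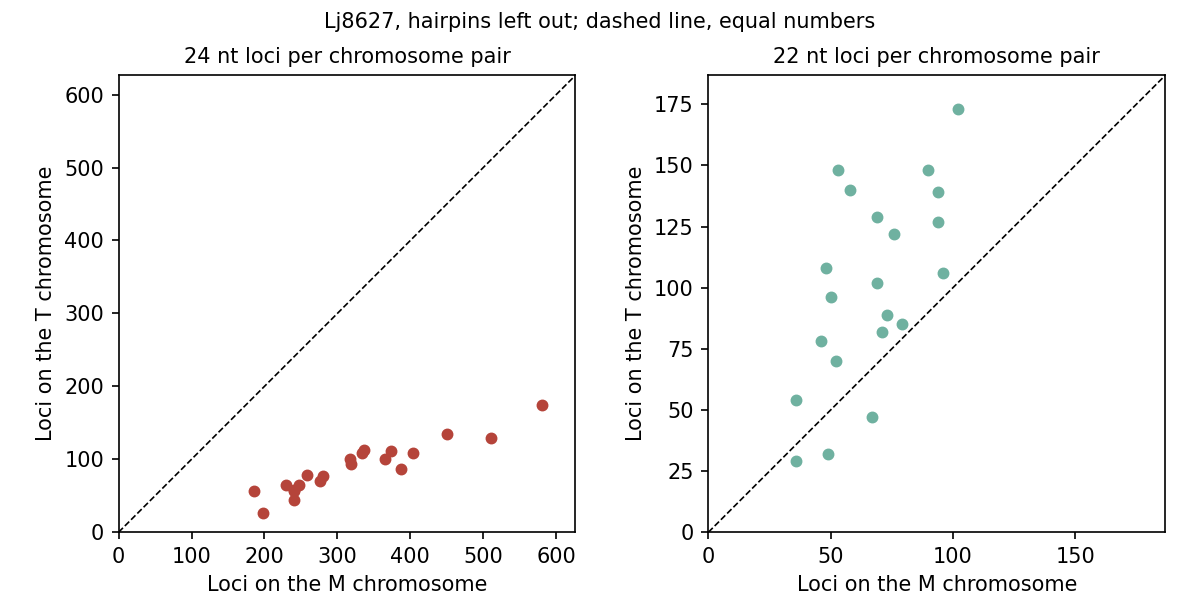
Each point is a pair of same-numbered chromosomes of Lj8627, with the number of loci on T and M chromosomes on the axes and a line of equality, for 24 nt and 22 nt loci outside hairpins. All 21 pairs have more 24 nt loci on M, and 18 of 21 have more 22 nt loci on T.

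Hairpins numbered 72 on M and 65 on T chromosomes, a ratio of 1.11. Its interval of 0.793 to 1.55 holds equality but also the 1.24 of 21 nt loci, so a small lean is not excluded. Per Mb spanned the hairpin ratio was 1.36. Matching by chromosome number, length and position of the mature strand gave 17 hairpin pairs and left 103 hairpins unpaired. Mature reads divided evenly, within binomial sampling noise, in 15 of the 17 pairs. On chr7 the M copy had 602031 mature reads and the T copy 602550, and on chr16 a pair had 598898 and 598874. The uneven pairs were on chr1, with 28 mature reads on M and 47 on T, and on chr16, with 22933 and 22049. Star reads were less even in some pairs, as on chr1 with 2 and 97. Mature sequences of the copies were not compared, so these values do not show whether reads of M and T copies were told apart. The even division is therefore no measure of equal expression from both copies.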

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

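Every test of an explanation in this part was chosen after the results had been seen. The balance of 24 nt against 21 and 22 nt loci differed in direction between accessions. On the log2 scale the ratio was 3.63 in Wa8730, while it was -0.80 in Lg7742a, -0.11 in Lj8627 and -0.93 in Sp9509. The difference was not tested, because the replicates of each accession are pooled, and the ratio of Lj8627 turns to 1.48 when 21 nt loci alone form the short class.

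As deposited, Wa8730 had 3.33 times as many 24 nt loci as Lj8627, the accession with the next most. With reads in loci scaled to the same total and at least 10 reads, it had 24.4 times as many as Sp9509, then the next. A difference in reads in loci or in the smallest count listed therefore does not account for the excess. The 24.4 is not per Mb, and Wa8730 spanned 351 Mb against 138 Mb in Sp9509. In the whole lists Wa8730 had 85.1 loci of 24 nt per Mb, against 7.52 in Sp9509. Against Lj8627, loci per Mb were 7.42 times as many, which argues against more chromosome sequence. The summed length of 24 nt loci was 4.51 times as large. Median listed length lay between 414 and 426 bp in every size class, and how much of it lies beyond the reads is not known. Summed length could therefore grow with the number of loci alone, and cannot decide on a finer division of the same sequence. Most reads in loci are hairpin reads and total library depth was not used, so library depth stays open, although at least 10 reads left 1167 loci of 21 nt in Wa8730 and 2194 in Lj8627. A difference between species, growth, library batches and the placement of reads at repeats were not tested and stay open too.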

How the results depend on the processing

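Chosen after seeing the data were the read minimums for the numbers and ratios of 24 nt loci, for long loci, for both chromosome sets at 10 reads and for the plus strand, the plus share of hairpins alone, and the windows of M and T chromosomes apart. The other alternatives were fixed before the data were examined. No paired analysis was possible because the 3 replicates of each accession are pooled, and for the same reason leaving out a replicate and a replicate block were not run. Adding 20 nt loci to the short class gave no value of its own, since no locus was called 20 nt. What depth limits was not measured, since total library depth was not used; the 24 nt loci of both Lemna accessions held a median of 5 reads, in lists that start at 3 reads. Wa8730 had the most 24 nt loci and the highest 24 nt share under every alternative run, while the order of the other 3 changed with the read minimum: Sp9509, the lowest in the whole lists, came second at 10 reads, and Lg7742a passed Lj8627 at 100 reads. Weighting by length also put Sp9509 above Lg7742a in share of loci, and leaving out the 10 top loci put Lg7742a above Sp9509 in share of reads. Where a minimum or a subset changed a value, the change follows from which loci were counted; beyond that the cause was not tested.

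With at least 5 reads, the number of 24 nt loci was 1288 in Lg7742a. With at least 10 reads it was 230 and 980 in Lg7742a and Lj8627, with at least 100 reads 21, 5, 108 and 698 in Lg7742a, Lj8627, Sp9509 and Wa8730, and with at least 10 scaled reads 230 and 728 in Lg7742a and Lj8627. The share of loci called 24 nt was 6.73%, 13.9%, 19.0% and 84.3% in Lg7742a, Lj8627, Sp9509 and Wa8730 with at least 10 reads. It was 2.73%, 0.512%, 11.5% and 48.7% in Lg7742a, Lj8627, Sp9509 and Wa8730 with at least 100 reads, and 6.73%, 11.6%, 20.4% and 84.2% in Lg7742a, Lj8627, Sp9509 and Wa8730 with at least 10 scaled reads. Over loci with a size call alone it was 33.6%, 44.2%, 32.8% and 91.3% in Lg7742a, Lj8627, Sp9509 and Wa8730, and weighted by length 19.3%, 31.3%, 20.4% and 83.7% in Lg7742a, Lj8627, Sp9509 and Wa8730. Leaving out hairpins, or sequences other than chromosomes, kept this share within its interval in each accession.

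The share of reads in 24 nt loci was 2.46%, 2.97%, 1.58% and 40.9% in Lg7742a, Lj8627, Sp9509 and Wa8730 without the 10 top loci. Without hairpins it was 3.34%, 5.22%, 2.33% and 51.7% in Lg7742a, Lj8627, Sp9509 and Wa8730. Over loci with a size call it was 0.766%, 1.18%, 0.807% and 13.4% in Lg7742a, Lj8627, Sp9509 and Wa8730, and on chromosomes alone 0.635%, 1.07%, 0.718% and 12.5% in Lg7742a, Lj8627, Sp9509 and Wa8730.

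Against 21 nt loci alone, the ratio of 24 nt loci was 0.745, 1.48, 0.756 and 19.7 in Lg7742a, Lj8627, Sp9509 and Wa8730, which turned the direction in Lj8627. Without the 10 top loci this ratio of loci stayed within its interval in all 4. With at least 10 reads it was 0.132, 0.249, 0.577 and 14.6 in Lg7742a, Lj8627, Sp9509 and Wa8730, and with at least 10 scaled reads 0.132, 0.203, 0.605 and 14.1 in Lg7742a, Lj8627, Sp9509 and Wa8730. The ratio of reads was 0.00870, 0.0147, 0.0116 and 0.178 in Lg7742a, Lj8627, Sp9509 and Wa8730 against 21 nt loci alone. It was 0.0363, 0.0389, 0.0210 and 1.11 in Lg7742a, Lj8627, Sp9509 and Wa8730 without the 10 top loci, which turned the direction in Wa8730. With at least 10 reads it was 0.00553, 0.00344 and 0.147 in Lg7742a, Lj8627 and Wa8730, and with at least 10 scaled reads 0.00553, 0.00293, 0.00784 and 0.138 in Lg7742a, Lj8627, Sp9509 and Wa8730.

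Hairpins with at least 100 reads numbered 58 in Wa8730, and with scaled reads 57 in Wa8730; the other accessions stayed within 1.5 times. The median length of 24 nt loci with at least 10 reads was 460 bp, 499 bp and 424 bp in Lg7742a, Lj8627 and Wa8730, and the mean length 432 bp, 437 bp, 715 bp and 591 bp in Lg7742a, Lj8627, Sp9509 and Wa8730. Their median reads with at least 10 reads were 14, 12 and 17 in Lg7742a, Lj8627 and Wa8730, and the mean reads 15.2, 6.58, 49.1 and 23.4 in Lg7742a, Lj8627, Sp9509 and Wa8730. With at least 100 reads, 24 nt loci on neither strand made up 4.76%, 20% and 98.9% in Lg7742a, Lj8627 and Wa8730. Windows of 500 kb with a 24 nt locus made up 84.9%, 90.4% and 86.3% in Lg7742a, Lj8627 and Sp9509, against 96.6%, 97.0% and 96.6% of 1 Mb windows.

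In Lj8627 the M to T ratio at 10 reads was 0.866 for 21 nt loci, a turn in direction, 0.396 for 22 nt loci and 7.26 for 24 nt loci. With at least 100 reads it was 1.81 for 21 nt loci and 4.00 for 24 nt loci, the latter from 4 loci on M and 1 on T. Per Mb spanned the ratios were 1.52, 0.824 and 4.49 for 21, 22 and 24 nt loci. Leaving out each chromosome pair in turn kept the 24 nt ratio between 3.59 and 3.69.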

Other observations

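Loci of 23 nt in Sp9509 differed from its 24 nt loci in strand. Of the 151 loci of 23 nt, 95.4% lay on a single strand, compared with 12.8% of its 1042 loci of 24 nt. In Lg7742a, Lj8627 and Wa8730 the single-strand shares of 23 nt loci were 50.0%, 38.5% and 36.2%. Within Sp9509, a 23 nt locus of 427 bp on chr10 from 1910233 to 1910659 held 9421 reads, 32.1% of the class, and a locus on chr8 from 4982522 to 4983104 held 24.7%. The fifth hairpin of Wa8730 by reads, on chr10 from 2614582 to 2614705, had no size call, and of its 61440 reads 6446 were of the mature and 39984 of the star strand.

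Chloroplast and mitochondrial sequences held few loci, mostly with no size call. The sequence named chrC, taken here as the chloroplast, had 62 loci in Lg7742a, 75 in Lj8627, 80 in Sp9509 and 53 in Wa8730, of which 49, 69, 72 and 46 had no call. They held 0.297%, 0.617%, 0.843% and 0.507% of reads. Star strands outnumbered mature strands in 7 hairpins of Lg7742a, 7 of Lj8627, 9 of Sp9509 and 5 of Wa8730. Hairpins less than 10 kb after the previous one numbered 11 in Wa8730, 6 in Sp9509, 5 in Lj8627 and 2 in Lg7742a.

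All tests of explanations in this part were chosen after the results had been seen. On M chromosomes of Lj8627, 24 nt loci were 3.65 times as many as on T chromosomes, within a lean of all loci to M of 1.75 and of loci with no size call of 1.56. With at least 10 reads, all loci were nearly even, with 3284 on M and 3229 on T, and loci with no size call numbered 981 and 791. A difference of dose or mapping that raises all classes of M alike, as the whole cause, runs against the 22 nt loci. Their ratio was 0.669, and 0.824 per Mb spanned. A part shared with other classes stays open. Loci near the smallest count are not the sole source of the excess, since the ratio with at least 10 reads was 7.26. Most of the excess loci nevertheless held fewer than 10 reads: 6771 against 1856 loci in the whole list became 791 against 109. The T chromosomes spanned 1.23 times the sequence of the M chromosomes, and whether their repeats are more alike, so that reads spread over copies until loci miss the threshold, cannot be told apart from a difference in 24 nt production without the genome sequence. Silencing itself was not measured here. Unequal 24 nt silencing of both chromosome sets may therefore be put forward only as a hypothesis.

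Of the loci assigned to a single strand, where no preference would give equal numbers, 60.6% were on the plus strand in Lj8627, 56.8% in Wa8730 and 54.2% in Lg7742a, against 50.5% in Sp9509. A few chromosomes in a single orientation cannot account for this, as plus was higher on 42 of 42 chromosomes of Lj8627, 20 of 20 of Wa8730 and 18 of 21 of Lg7742a. With at least 10 reads the plus share was 59.9% in Lj8627 and 57.1% in Wa8730, so loci with fewer than 10 reads alone do not account for it there, whereas in Lg7742a it was 48.8% against 57.9% below 10 reads, which is consistent with an excess carried by those loci. With at least 100 reads the excess was gone in Lj8627, at 49.0% (45.4 to 52.5) after 62.9% at 10 to 99 reads, and was 55.7% (51.6 to 59.7) in Wa8730. The plus share in Lj8627 also differed by class outside hairpins, from 54.0% in loci with no size call to 72.4% in 22 nt loci. It was 64.5% on T and 57.2% on M chromosomes. Placement of reads that match repeats is open, because repeats were not identified (hairpins of Lj8627 lay on the plus strand in 50.0% of cases, 41.9 to 58.1), and no biological explanation was tested.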
